A study of Mus musculus with 15 samples.

How the data were processed

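RNA sequencing was analysed for 15 libraries of E0771 cells in 5 groups of 3: empty vector, Malt1_WT, Malt1_PD, Malt1_V87R and Malt1_L88D. Per the labels, total RNA was made into stranded libraries (NEBNext Ultra II Directional) and read as paired ends of 150 bp. The authors deposited unnormalised counts per gene symbol, and their processing notes name Trim Galore 0.6.0, STAR 2.7.3a, featureCounts 1.6.3 and the build GRCm38.p6. The annotation release, the strand setting and the handling of reads that map to several genes are not given in the sources used here. All values in the table were whole numbers. It had 55571 gene rows, of which 22982 were 0 in every library, and 55341 matched a symbol in GENCODE M21, the annotation used here for positions. The other 230 held 0.0308% of counts.

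Groups were taken from the column names. The columns for Malt1_PD carry the name of a cysteine substitution instead, and were assigned to that group because it was the only Malt1 construct without columns of its own name. Both V87 and L88 are present in the mouse protein of 821 residues, as is the cysteine. The labels do not say whether replicates are separate cultures, or whether each construct is in a pool or a clone of cells.

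Library totals ran from 15.5 M to 21.5 M counts (M, counts divided by 1e6), with group means of 19.15 M for vector, 16.26 M for Malt1_WT, 18.5 M for Malt1_PD, 20.28 M for Malt1_V87R and 17.73 M for Malt1_L88D. A count of 0 allows up to 3 counts, and such limits cover counting error only. CPM values used totals scaled by TMM factors, which ran from 0.9733 to 1.0153.

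Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr with the groups left 14571 genes, and a robust quasi-likelihood fit of all 15 libraries with 1 mean per group gave 8 two-sided comparisons, each adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. The comparisons were each construct against the vector, each mutant against Malt1_WT, and Malt1_V87R against Malt1_L88D. The common biological coefficient of variation was 4.61%. Intervals are at 95%.

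The 27 gene lists were fixed before the data were examined: MALT1 complex, MALT1 substrates, NF-kB targets, Regnase-1 and Roquin targets, interferon-stimulated genes, MHC class I, checkpoint and T or NK cell ligands, cytokines and chemokines, AP-1 and immediate-early genes, YAP/TEAD targets, S-phase, G2/M, p53 targets, hypoxia and glycolysis, unfolded protein and integrated stress response, cholesterol synthesis, epithelial, mesenchymal, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, mitochondrially encoded genes, histones, and markers of T and NK cells, macrophages and dendritic cells, fibroblasts and endothelium. Lists overlap in membership. Each was tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. The directional test of fry, which does not compare a list with other genes, was run as an alternative. List counts come from the test over all genes and, separately, from adjusting over the list alone.

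Malt1 was named first. The other named genes followed a rule set before the data were examined. Among genes with an adjusted p under 0.05, no overlap between the libraries of the groups (10% of genes with no change do so by chance with 3 against 3) and a mean of at least 5 CPM in the higher group, leaving out Malt1 and predicted or unnamed symbols, it took the 6 largest rises and 6 largest falls. It took 4 and 4 for Malt1_V87R or Malt1_L88D against vector, and 3 and 3 between them. From each list described it took up to 4 called members with the smallest adjusted p, or up to 2 of highest CPM where none was called. Values of a named gene are also given in comparisons other than the one that named it. Those genes were chosen for that second comparison after their values were seen.

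Correlations of effects over genes were set against 20 simulations in which all 15 libraries, the vector included, were drawn from the vector means. The pair of Malt1_V87R and Malt1_L88D was added after the data were seen. Shares of wild-type effects were set against 5 simulations in which each mutant equalled the wild type.

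The test was tried on simulated data. With 50 genes changed at each size in the design of Malt1_WT against vector, 48% were recovered at 1.25-fold, 70% at 1.5-fold, 86% at 2-fold and 94% at 4-fold, and 14 of 163 calls (8.6%) were of genes not changed. In that of Malt1_V87R against Malt1_L88D the shares were 44%, 80%, 74% and 96%, with 11 of 158 calls (7%) of genes not changed. Camera found the 1 list that was shifted and called 0 of 25 others. Genes were drawn independently in these data, so this does not test camera on lists of correlated genes. The estimated correlation of the real ribosomal protein list, for example, was 0.866.

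Alternatives planned beforehand were RLE scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, a fit of only the 6 libraries compared, replicate number as a block, Malt1 left out, and leaving out each library in turn. Upper-quartile scaling and no scaling factor were added after the data were seen. Outliers within groups were not tested with 3 libraries each. No column of the table was left out.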

Results

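Gene expression was measured by RNA sequencing in E0771, a mouse mammary carcinoma cell line, carrying an empty vector or 1 of 4 forms of Malt1. MALT1 is a paracaspase that joins BCL10 and a CARD protein in a complex upstream of NF-kB, where it acts both as a scaffold and as a protease. The forms were the wild type (Malt1_WT), a mutant named PD in the labels (Malt1_PD), and the substitutions V87R and L88D (Malt1_V87R and Malt1_L88D), which lie next to each other in the N-terminal death domain, the part that binds BCL10. The Malt1_PD values are in columns named for a substitution of a cysteine in the protease domain, and the labels do not spell out what PD stands for. Per the series title the cells were not cocultured with T cells, and each of the 5 groups had 3 libraries. Total counts per library ran from 15471746 to 21458457. All ± values in CPM, counts scaled to a library total of 1e6, are SD over n = 3 libraries. The ± values of log2 fold changes are standard errors (SE).

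Malt1 itself (gene ENSMUSG00000032688.9, GRCm38 chromosome 18, 65430938 to 65479067, plus strand, protein coding) was first compared in every library. Its level was 28.1 ± 1.92 CPM with the vector, 202 ± 7.96 CPM in Malt1_WT, 250 ± 8.86 CPM in Malt1_PD, 279 ± 1.35 CPM in Malt1_V87R and 251 ± 6.73 CPM in Malt1_L88D. Against the vector these were rises of 7.20-, 8.91-, 9.96- and 8.96-fold (edgeR adjusted p from 7.4e-27 to 5.8e-28). All 3 mutants had more Malt1 mRNA than the wild type, by 0.31 ± 0.04 (SE) on the log2 scale for Malt1_PD (adjusted p = 2.6e-06), 0.47 ± 0.04 for Malt1_V87R (adjusted p = 1.6e-10) and 0.32 ± 0.04 for Malt1_L88D (adjusted p = 3.5e-07). The gene count cannot tell construct transcripts from endogenous ones, and it does not read the substitutions.

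**Figure D1:**
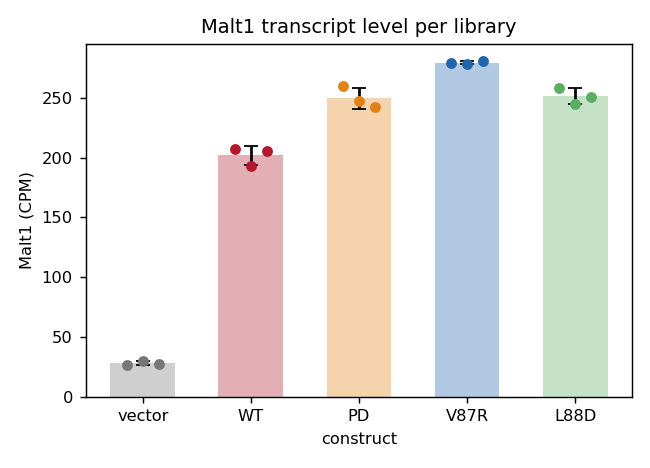
Malt1 in CPM for each of the 15 libraries (points), with the mean of each construct (bar, from 0) and its SD over 3 libraries (error bar). The vector libraries sit between 26.4 and 30.2 CPM and the libraries of all 4 Malt1 constructs between 193 and 281 CPM.

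The comparison of Malt1_WT with the vector asked what the wild-type protein changes in the tumour cells. Inflammatory cytokine and chemokine genes made up 5 of the 6 largest rises among genes of at least 5 CPM whose groups did not overlap. Cxcl9, a chemokine that attracts T cells, went from 0.490 ± 0.265 to 163 ± 8.19 CPM (log2 fold change 8.29 ± 0.15 SE). Ccl3, a macrophage-attracting chemokine, went from 2.97 ± 0.318 to 357 ± 19.3 CPM. The interleukin gene Il1b rose 70.6-fold from 0.205 ± 0.035 CPM, the neutrophil chemokine Cxcl2 from 4.09 ± 0.583 to 274 ± 9.17 CPM, and Csf3, the granulocyte colony-stimulating factor, from 7.03 ± 0.624 to 398 ± 22.8 CPM. Fgf23, a hormone of phosphate balance, was the other and rose by 6.61 ± 0.23 on the log2 scale. Mitotic genes fell together, with Mki67, the antigen of the Ki-67 proliferation stain, at 50.3 ± 1.79 against 226 ± 5.63 CPM.

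Of the 56 NF-kB target genes tested, 53 rose and 1 fell in Malt1_WT, with the same 53 and 1 when adjusted over the list alone (median log2 fold change 1.69, camera adjusted p = 4.1e-31, and adjusted p = 0.0072 with an estimated correlation). Il1a rose 45.9-fold, Cxcl1 8.63-fold and Nos2, the inducible nitric oxide synthase, 7.30-fold to 2349 ± 76.9 CPM. Of the 34 cytokine and chemokine genes, 29 rose and 2 fell, the counts also reached when adjusted over the list alone (median 2.81, adjusted p = 0.011 with an estimated correlation). Il6 rose from 17.1 ± 0.547 to 291 ± 7.22 CPM. Among mRNAs that the RNA-degrading proteins Regnase-1 and Roquin are known to target, 19 of 20 rose, also when adjusted over the list alone (median 1.48, adjusted p = 0.0058 with an estimated correlation), among them Ptges, a prostaglandin E synthase, by 4.44-fold. Most mRNAs on this list, Ptges included, are also on the NF-kB target list. Its counts are therefore largely not separate from those of that list, here and in the comparisons below. Of 13 genes that encode known MALT1 protease substrates, 9 rose and none fell, or 10 adjusted over the list alone (adjusted p = 0.014 with an estimated correlation), including the NF-kB inhibitor Tnfaip3 (5.23-fold), Zc3h12a, which encodes Regnase-1 (1.89-fold), and the NF-kB subunit gene Relb (48.4 ± 1.99 against 24.2 ± 1.06 CPM). AP-1 and immediate-early genes rose in 20 of 26 cases and fell in 1, or 21 and 1 adjusted over the list alone (median 0.73, adjusted p = 0.013 with an estimated correlation), with Phlda1 at 3.65-fold and Junb at 2.01-fold.

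Interferon-stimulated genes rose in 33 of 40 cases and fell in 1, the same adjusted over the list alone (median 0.57). The camera call of this list was lost with an estimated correlation, at adjusted p = 0.11. Gbp2 (9.53-fold) and Igtp (4.69-fold), both interferon-inducible GTPases, and the poly-ADP-ribose polymerase gene Parp14 (4.07-fold) had the smallest adjusted p. All 20 tested genes of MHC class I antigen presentation rose, also when adjusted over the list alone (median 0.67, adjusted p = 0.022 with an estimated correlation). They included the peptide transporter gene Tap1 (3.11-fold), the peptide editor gene Tapbpl (4.78-fold) and Nlrc5, the transcriptional activator of class I genes (144 ± 9.40 against 53.4 ± 3.64 CPM). Among 18 checkpoint and T or NK cell ligand genes, 9 rose and 7 fell, the same adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.18). Cd274, the checkpoint ligand that engages Pdcd1 on T cells, rose from 5.45 ± 0.555 to 175 ± 4.77 CPM (32.3-fold), and Pvr, a ligand of NK cell receptors, rose 3.93-fold.

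Genes of cell division moved the other way. All 29 tested G2/M genes fell, also when adjusted over the list alone (median -1.78, adjusted p = 0.0058 with an estimated correlation). Of 30 S-phase and E2F target genes, 29 fell, again 29 over the list alone (median -0.74, adjusted p = 0.013 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was at 33.5 ± 1.81 against 164 ± 10.2 CPM, and the ribonucleotide reductase gene Rrm2 at 193 ± 2.92 against 395 ± 9.01 CPM. Replication-dependent histone genes fell in 10 of 13 cases, or 12 adjusted over the list alone (adjusted p = 0.017 with an estimated correlation). Of 20 p53 target genes, 13 rose and 3 fell, the same over the list alone (adjusted p = 0.022 with an estimated correlation), and the cyclin-dependent kinase inhibitor gene Cdkn1a reached 1042 ± 41.3 against 283 ± 5.72 CPM.

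Genes of the unfolded protein and integrated stress responses rose in 29 of 33 cases and fell in 1, the same adjusted over the list alone (median 0.70, adjusted p = 0.014 with an estimated correlation), including the endoplasmic reticulum chaperone Hspa5 (2.48-fold), the mitochondrial folate enzyme Mthfd2 (2.45-fold) and Trib3 (2.97-fold). Cholesterol synthesis genes fell in 20 of 25 cases and none rose, the same over the list alone (median -0.72, adjusted p = 0.011 with an estimated correlation). Under the same rule, the largest fall was in the matricellular gene Ccn5, from 13.0 ± 1.47 to 0.103 ± 0.035 CPM, followed by Gprc5b, Akr1cl, Rgcc, Ldb2 and Fam83d, which had log2 fold changes of -3.64, -3.22, -2.72, -2.63 and -2.62.

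Markers of other cell types also moved. Of 11 tested macrophage and dendritic cell markers, 7 rose and 1 fell, the same over the list alone (median 1.07), a call lost with an estimated correlation at adjusted p = 0.19. The summed level of the 20 markers listed was 79.0 ± 1.47 in Malt1_WT, 84.1 ± 2.61 in Malt1_PD, 45.7 ± 1.69 in Malt1_V87R and 59.6 ± 11.7 in Malt1_L88D against 47.5 ± 1.47 CPM with the vector, and Cd14 rose 2.92-fold and Cd68 2.09-fold in Malt1_WT. Of the T and NK cell markers only Lck, a kinase of T cells, passed the expression filter, and it rose from 1.64 ± 0.267 to 2.79 ± 0.541 CPM.

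In all, 7997 of 14571 tested genes differed between Malt1_WT and the vector (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 3958 higher and 4039 lower, of which 1144 rose and 526 fell by at least 2-fold. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Nor do the labels say whether a construct is in a pool or a clone of cells. In all comparisons, differences between lines of cells therefore cannot be told apart from effects of the constructs. Members of near-identical families (the Gbp and Irgm GTPases, the H2-Q class I genes, Ifit3 and Ifit3b, Oas1a and Oas1b, histones) can share reads, so their individual values are uncertain.

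**Figure D2:**
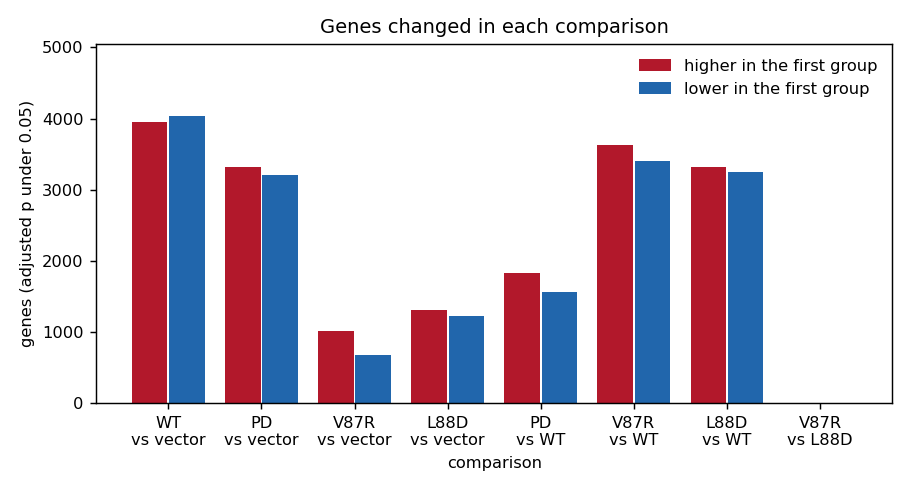
Number of genes with an adjusted p under 0.05 in each of the 8 comparisons (bars from 0), split into genes higher and lower in the first-named group. Malt1_WT against vector had 3958 higher and 4039 lower genes, and Malt1_V87R against Malt1_L88D had 0.

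The comparison of Malt1_PD with the vector asked what the PD form changes by itself. Inflammatory genes again rose and cell division genes fell. Ccl3 rose to 209 ± 20.3 CPM (71.0-fold), Cxcl2 to 180 ± 5.57 CPM (43.8-fold), Il1b to 6.28 ± 0.025 CPM (29.6-fold) and the tumour necrosis factor gene Tnf to 40.2 ± 3.64 from 1.11 ± 0.380 CPM (34.9-fold). Ceacam15 and Fgf23 rose 44.4- and 38.9-fold. Ccn5 fell to 0.409 ± 0.172 CPM, and Gprc5b, Col8a1, Ldb2, Rgcc and Akr1cl fell to between 0.136 and 0.209 of their vector level.

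NF-kB target genes rose in 53 of 56 cases and fell in 1 in Malt1_PD, or 53 and 2 adjusted over the list alone (median 1.602, adjusted p = 0.0046 with an estimated correlation). Cytokine and chemokine genes rose in 28 of 34 cases and fell in 1, the same over the list alone (median 1.502, adjusted p = 0.0066 with an estimated correlation), with the macrophage growth factor Csf1 at 723 ± 31.0 against 156 ± 2.06 CPM. Regnase-1 and Roquin targets rose in 17 of 20 cases, or 17 up and 1 down over the list alone (adjusted p = 0.0046 with an estimated correlation). Substrate genes rose in 8 of 13, or 9 over the list alone (adjusted p = 0.014 with an estimated correlation). AP-1 and immediate-early genes rose in 21 of 26 cases and fell in 1, the same over the list alone (adjusted p = 0.0066 with an estimated correlation). Stress-response genes rose in 30 of 33 cases, also over the list alone (median 0.83, adjusted p = 0.0066 with an estimated correlation), with Hspa5 at 2.94-fold. All 29 G2/M genes (median -1.11, adjusted p = 0.0046 with an estimated correlation) and all 30 S-phase genes (median -0.73, adjusted p = 0.0066 with an estimated correlation) fell, also over the list alone. Cholesterol genes fell in 20 of 25 cases and rose in 2, or 21 and 2 over the list alone (adjusted p = 0.019 with an estimated correlation). Histone genes fell in 9 of 13 cases, or 10 over the list alone, and p53 target genes rose in 11 of 20 and fell in 3 (adjusted p = 0.019 with an estimated correlation for each list). Interferon-stimulated genes rose in 34 of 40 cases, also over the list alone (median 0.36), and MHC class I genes in 16 of 20 with 1 fall, also over the list alone (median 0.38). Both calls were lost with an estimated correlation, at adjusted p = 0.12 and 0.11. Parp14 rose 2.42-fold and Gbp2 1.98-fold, and Cd274 rose 4.04-fold to 21.9 ± 1.65 CPM. Macrophage and dendritic cell markers rose in 9 of 11 cases and fell in 1, the same over the list alone (median 1.36), a call lost with an estimated correlation at adjusted p = 0.11. In all, 6521 genes changed, 3318 up and 3203 down, of which 775 rose and 369 fell by at least 2-fold.

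The direct comparison of Malt1_PD with Malt1_WT asked how cells with the PD form differ from those with the wild type. The 6 largest falls, under the rule used above, included 4 interferon-inducible genes. Cxcl9 was at 1.32 ± 0.501 in Malt1_PD against 163 ± 8.19 CPM in Malt1_WT (log2 fold change -6.96 ± 0.13 SE). The GTPase genes were lower too, with Gbp4 at 3.36 ± 0.620 CPM (-3.63 ± 0.10) and Iigp1 at 13.9 ± 1.90 against 102 ± 6.54 CPM, and Cd274 at 21.9 ± 1.65 against 175 ± 4.77 CPM. Il12b, an interleukin subunit, and Apol10b had differences of -2.92 and -2.89 on the log2 scale. The transcription factor gene Irf1 was at 102 ± 4.60 against 422 ± 21.4 CPM, Nlrc5 at 0.388 and Tap1 at 0.415 of the wild-type level, and Nos2 at 0.427 of it. G2/M genes were higher, with 28 of 29 up, also over the list alone (median 0.61, adjusted p = 0.0046 with an estimated correlation), among them Cdc20 (2.10-fold) and Plk1 (2.04-fold).

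In Malt1_PD against Malt1_WT, interferon-stimulated genes fell in 21 of 40 cases and rose in 7, or 22 and 7 over the list alone. MHC class I genes fell in 14 of 20 and rose in 2 (16 and 2 over the list alone). NF-kB target genes fell in 26 of 56 and rose in 9 (30 and 9 over the list alone). Cytokine genes fell in 20 of 34 and rose in 4 (21 and 6 over the list alone), and Regnase-1 and Roquin targets fell in 12 of 20 (14 over the list alone). The camera calls of these 5 lists were lost with an estimated correlation, at adjusted p = 0.28, 0.072, 0.20, 0.10 and 0.065 in that order. Il6 was lower at 121 ± 5.90 CPM and the growth factor gene Csf2 at 25.8 ± 2.82 against 62.7 ± 6.15 CPM, while the chemokine Ccl7 was higher at 691 ± 40.5 against 416 ± 3.98 CPM. Cholesterol genes rose in 18 of 25 cases, or 19 with 1 fall over the list alone (median 0.38, adjusted p = 0.016 with an estimated correlation). The S-phase list was not called (camera adjusted p = 0.35), with 1 member up and 4 down, the same over the list alone. Collagen genes Col6a1 and Col6a2 were higher by 1.94- and 1.87-fold, in a mesenchymal and matrix list that was not called (camera adjusted p = 0.083), with 10 of 27 members up and 4 down, or 10 and 7 over the list alone. Fibroblast markers summed to 799 ± 14.9 CPM in Malt1_PD against 669 ± 4.41 CPM in Malt1_WT and 660 ± 10.4 CPM with the vector, with 3 of 10 up and 1 down, or 4 and 1 over the list alone (camera adjusted p = 0.11). Endothelial markers summed to 129 ± 5.49 against 148 ± 7.25 CPM in Malt1_WT, with 3 of 7 down and 0 up, or 3 and 1 over the list alone (camera adjusted p = 0.15). Apart from Cdc20, the largest rises were the angiotensinogen gene Agt (6.99 ± 0.470 against 0.994 ± 0.090 CPM), Cdkn3, Idh1 and the macrophage-enriched genes Apoe (11.5 ± 0.836 against 5.40 ± 0.326 CPM) and Lyz2 (14.3 ± 1.38 against 4.64 ± 2.26 CPM). Beside them C1qb, another macrophage gene, was at 0.541 ± 0.263 against 0.0409 ± 0.036 CPM, while of the 11 tested macrophage and dendritic cell markers 3 rose and 2 fell, or 3 and 3 over the list alone (camera adjusted p = 0.94).

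Malt1_PD differed from Malt1_WT in 3399 genes, 1834 higher and 1565 lower, of which 41 rose and 213 fell by at least 2-fold. With upper-quartile scaling, a setting chosen after seeing the data, the split was 1365 higher and 1766 lower. The number of higher genes fell to 1201 with only the 6 libraries compared, 1159 without Malt1_WT replicate 2, 1207 without replicate 3, 1107 without Malt1_PD replicate 1 and 1177 without replicate 3. Without Malt1_PD replicate 2, all counts were larger (4068 genes, 2085 higher and 1983 lower). The call of Lyz2 was lost in 5 of 16 alternatives, including without Malt1_WT replicate 1 or 3 or Malt1_PD replicate 1 or 3.

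Malt1_V87R and Malt1_L88D were each compared with the vector, to see what remained of the response with a changed death domain. The 4 largest rises were the same in both mutants and were all interferon-inducible genes. Cxcl9 rose to 36.5 ± 1.55 CPM in Malt1_V87R (70.0-fold) and 31.2 ± 3.10 CPM in Malt1_L88D (59.6-fold), Cd274 to 200 ± 8.71 and 182 ± 3.29 CPM (36.8- and 33.6-fold), Gbp4 by 4.39 and 4.30 on the log2 scale, and Iigp1 to 194 ± 6.69 and 189 ± 9.11 from 9.66 ± 0.544 CPM. Irf1 rose 6.34- and 6.13-fold and the immunoproteasome subunit gene Psmb9 3.66- and 3.89-fold. The 4 largest falls among genes of at least 5 CPM whose groups did not overlap were in Wfdc1, Lrrc15, Gprc5b and Tent5b for Malt1_V87R and in Hist1h1c, Gprc5b, Lrrc15 and Kctd14 for Malt1_L88D, with levels between 0.517 and 0.564 of the vector. Among all tested genes, 183 rose and 17 fell by at least 2-fold in Malt1_V87R, and 233 and 21 in Malt1_L88D.

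Interferon-stimulated genes rose in 33 of 40 cases in Malt1_V87R and 34 in Malt1_L88D, or 37 and 36 adjusted over the list alone (medians 0.55 and 0.60, adjusted p = 0.0091 and 0.013 with an estimated correlation). Igtp rose 7.01- and 6.74-fold and Irgm1, another interferon-inducible GTPase, 3.85- and 3.70-fold. MHC class I genes rose in 17 of 20 cases in both, with 0 and 1 falls, the same over the list alone (medians 0.77 and 0.78, adjusted p = 0.0060 and 0.011 with an estimated correlation). NF-kB target genes rose in 38 of 56 cases in both, or 39 and 40 over the list alone (medians 0.42 and 0.45, adjusted p = 0.0060 and 0.011 with an estimated correlation). Cytokine genes rose in 23 and 21 of 34, with 2 and 1 falls, or 24 and 22 up with 3 down each over the list alone (adjusted p = 0.0091 and 0.011 with an estimated correlation). Il6 rose 2.31- and 2.11-fold and Cxcl10, an interferon-inducible chemokine, 6.64- and 6.59-fold. Regnase-1 and Roquin targets rose in 14 and 15 of 20 cases, or 16 each over the list alone (adjusted p = 0.0060 and 0.011 with an estimated correlation). Substrate genes rose in 4 and 5 of 13, or 4 and 6 over the list alone (adjusted p = 0.032 and 0.055 with an estimated correlation). G2/M genes fell in 24 and 23 of 29 cases, with 1 and 0 rises, or 25 down and 1 up each over the list alone (medians -0.25 and -0.27, adjusted p = 0.0091 and 0.011 with an estimated correlation). Cdc20 was at 0.699 and 0.642 of the vector level. Histone genes fell in 3 and 5 of 13, or 4 and 6 over the list alone (adjusted p = 0.0091 and 0.011 with an estimated correlation). The AP-1 and immediate-early list was not called in either (camera adjusted p = 0.55 and 0.39), with 4 and 6 members up and 5 and 4 down, or 5 and 7 up and 6 and 4 down over the list alone. Neither was the cholesterol list (0.055 and 0.87), with 6 and 3 up and 1 down in each, or 7 and 3 up over the list alone. Macrophage and dendritic cell markers rose in 1 and 4 of 11 cases and fell in 0, or 1 and 6 up over the list alone, and the list was not called (camera adjusted p = 0.99 and 0.066). In Malt1_L88D C1qb was at 0.535 ± 0.259 against 0.0719 ± 0.064 CPM with the vector, and Apoe, which was not called, at 11.4 ± 4.12 against 8.33 ± 0.923 CPM. The call of C1qb was lost without vector replicate 3 or Malt1_L88D replicate 2. Fibroblast markers summed to 616 ± 11.7 and 614 ± 0.584 against 660 ± 10.4 CPM with the vector, with 1 and 3 of 10 down and 0 up. Endothelial markers summed to 145 ± 4.94 and 144 ± 3.86 against 124 ± 4.41 CPM, with 1 of 7 up and 1 down in each. Neither list was called (camera adjusted p = 0.053 and 0.073 for fibroblast, 0.69 and 0.92 for endothelial markers).

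Against the vector, 1704 genes changed in Malt1_V87R (1021 up, 683 down) and 2535 in Malt1_L88D (1307 up, 1228 down). Without Malt1_V87R replicate 2 the first count was 1130 (773 up, 357 down), and without vector replicate 1 the second was 1545 (972 up, 573 down). The number of lowered genes also moved by over 1.5 times in Malt1_V87R without vector replicate 1 (386) or 3 (380) or Malt1_V87R replicate 1 (433), and in Malt1_L88D without vector replicate 3 (684) or Malt1_L88D replicate 2 (711) or 3 (702).

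**Figure D3:**
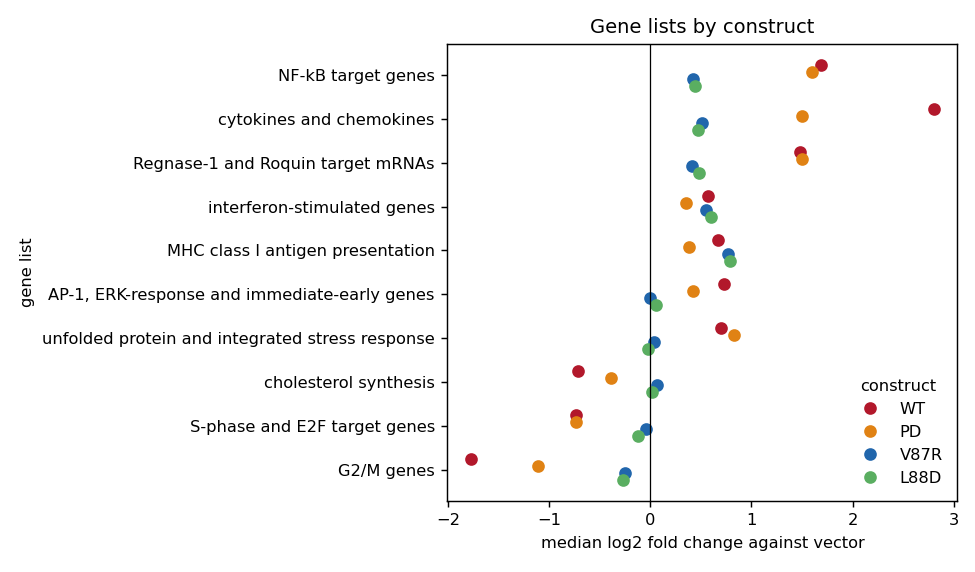
Median log2 fold change against the vector (horizontal axis) of the tested members of 10 gene lists (vertical axis), with 1 point per construct. NF-kB target genes had medians of 1.691 and 1.602 in Malt1_WT and Malt1_PD and of 0.42 and 0.45 in Malt1_V87R and Malt1_L88D, while the interferon-stimulated list lay between 0.36 and 0.60 in all 4.

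Malt1_V87R and Malt1_L88D were then set against Malt1_WT directly. The inflammatory genes were far lower in both, with Il1b at 0.244 ± 0.038 and 0.226 ± 0.032 CPM (log2 fold changes -5.90 and -6.03), Ccl3 at 6.83 ± 0.457 and 6.07 ± 1.23 against 357 ± 19.3 in Malt1_WT, Il1a at 14.7 ± 0.842 and 13.7 ± 0.933 against 404 ± 9.38, and Cxcl2 at 10.2 ± 1.08 and 10.3 ± 1.14 against 274 ± 9.17. Ceacam15 had log2 fold changes of -5.25 and -4.82. Ccn5 was 66.0- and 68.7-fold higher, at 7.29 ± 0.764 and 7.59 ± 0.861 CPM, and Akr1cl, Gprc5b, Rgcc, Col8a1 and the isocitrate dehydrogenase gene Idh1 were 5.13- to 8.30-fold higher. Mki67 was 3.67-fold higher in Malt1_V87R, and all 29 G2/M genes were higher in both, also over the list alone (medians 1.52 and 1.39, adjusted p = 0.0051 and 0.0056 with an estimated correlation).

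Compared with Malt1_WT, 50 of 56 NF-kB target genes were lower in each of Malt1_V87R and Malt1_L88D, with 2 and 1 higher, or 50 and 51 lower with 2 higher each over the list alone (medians -1.26 and -1.29, adjusted p = 0.0055 and 0.0057 with an estimated correlation). Cytokine genes were lower in 27 of 34 cases with 3 higher in both, or 27 and 28 lower over the list alone (medians -2.10 and -2.18, adjusted p = 0.0087 and 0.0082 with an estimated correlation). Regnase-1 and Roquin targets were lower in 19 and 18 of 20 cases, or 19 each over the list alone (adjusted p = 0.0051 and 0.0056 with an estimated correlation). AP-1 and immediate-early genes were lower in 23 and 22 of 26 with 1 higher, or 24 and 22 (adjusted p = 0.0051 and 0.0062 with an estimated correlation). Stress-response genes were lower in 32 of 33 in both, with 1 and 0 higher, also over the list alone (adjusted p = 0.0087 and 0.0077 with an estimated correlation). S-phase genes were higher in 29 and 28 of 30 cases, or 29 each over the list alone (adjusted p = 0.0087 and 0.0096 with an estimated correlation). Cholesterol genes were higher in 23 of 25, also over the list alone (adjusted p = 0.0051 and 0.0057 with an estimated correlation). The interferon-stimulated list was not called (camera adjusted p = 0.65 and 0.46), with 12 members higher and 10 lower in both, or 14 and 10 in Malt1_V87R over the list alone. Nor was the MHC class I list (0.31 and 0.29), with 6 higher and 9 lower in both, also over the list alone. Interferon-inducible genes thus went both ways. Iigp1 was higher than in Malt1_WT by 0.93 and 0.90 on the log2 scale, while Cxcl9 had differences of -2.16 and -2.39 and the antiviral gene Rsad2 was at 0.502 and 0.543 of the wild-type level. Cd274 was higher in Malt1_V87R by 0.19 (adjusted p = 0.00099) and was not called in Malt1_L88D (0.06, adjusted p = 0.33). Macrophage and dendritic cell markers were lower in 7 and 5 of 11 cases with 1 and 2 higher, or 7 and 6 lower with 1 and 3 higher over the list alone. The list was called in Malt1_V87R only (camera adjusted p = 0.0084 and 0.090), and that call was lost with an estimated correlation (adjusted p = 0.19). Endothelial markers were lower in 4 and 3 of 7 cases with 0 and 1 higher, a list not called (0.17 and 0.23).

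Malt1_V87R differed from Malt1_WT in 7036 genes (3625 higher, 3411 lower) and Malt1_L88D in 6569 (3321 higher, 3248 lower). Of the 3958 genes higher in Malt1_WT than with the vector, 3016 (76.2%) were lower in Malt1_V87R than in Malt1_WT, 2853 (72.1%) in Malt1_L88D and 1274 (32.2%) in Malt1_PD. Because Malt1_WT enters both tests, the same share was computed in 5 simulated data sets in which each mutant equalled the wild type, where it was at most 0.05%. With no real difference there, few genes can be called, so this value does not measure the selection at the cutoff of the real data. Among all 14571 tested genes, 3411 were lower than in Malt1_WT in Malt1_V87R, 3248 in Malt1_L88D and 1565 in Malt1_PD.

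**Figure D4:**
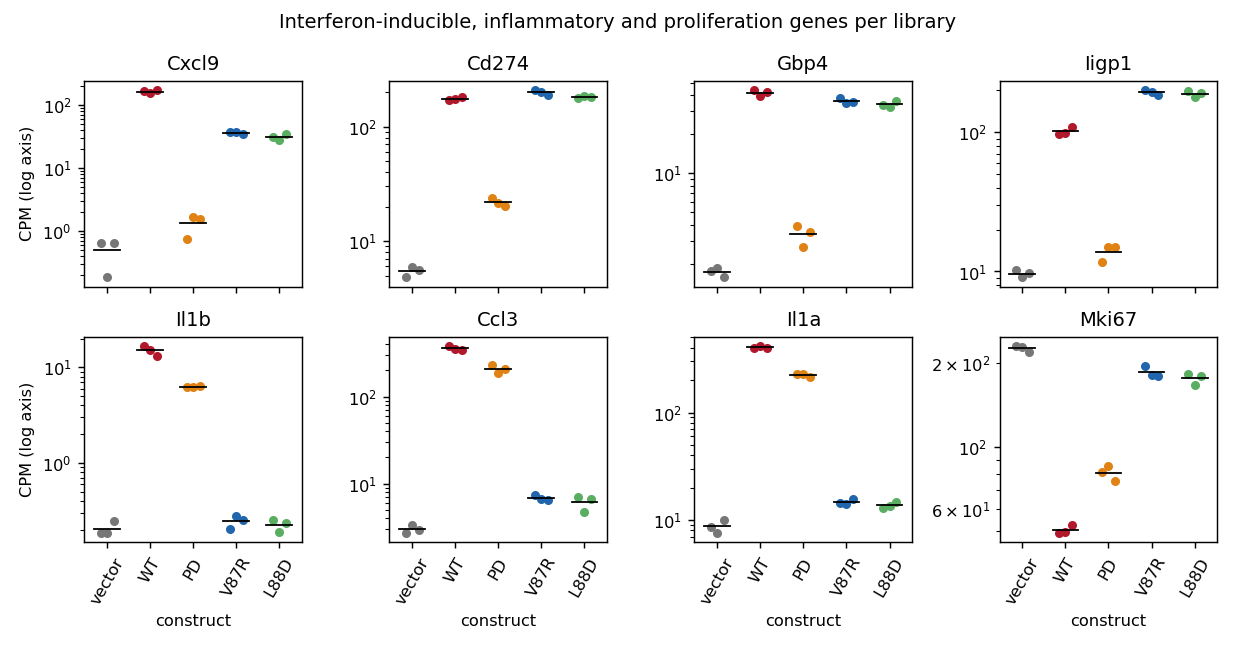
CPM on a log axis in each of the 15 libraries (points) with the group mean (line) for 4 interferon-inducible genes (Cxcl9, Cd274, Gbp4, Iigp1), 3 inflammatory genes (Il1b, Ccl3, Il1a) and the proliferation gene Mki67. Cd274 was at 175, 200 and 182 CPM in Malt1_WT, Malt1_V87R and Malt1_L88D and at 21.9 CPM in Malt1_PD, whereas Ccl3 was at 357 and 209 CPM in Malt1_WT and Malt1_PD and at 6.83 and 6.07 CPM in Malt1_V87R and Malt1_L88D.

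No gene differed between Malt1_V87R and Malt1_L88D by the edgeR test. The lowest adjusted p was 0.42, 852 genes (5.8%) had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The same edgeR test called 25 genes with only the 6 libraries compared, 5 with no filter on low counts and 2 without Malt1_L88D replicate 1. Among 9888 genes with a mean of at least 5 CPM, the 95% interval of the difference lay within 1.5-fold for 98.7% and within 2-fold for 100%. Genes picked after their values were seen show the size of these intervals. Malt1_V87R minus Malt1_L88D on the log2 scale was 0.15 (0.06 to 0.25) for Malt1, 0.23 (0.04 to 0.42) for Cxcl9, -0.02 (-0.22 to 0.19) for Cxcl2, 0.07 (-0.03 to 0.17) for Mki67 and 0.01 (-0.06 to 0.09) for B2m. Macrophage and dendritic cell markers had the median farthest from 0 among the 10 lists called by camera here (-0.30, camera adjusted p = 0.0024), with 0 of 11 members called over all genes and 5 lower in Malt1_V87R when adjusted over the list alone. Without Malt1_L88D replicate 2 that list was not called (adjusted p = 0.0514). Of the mitochondrially encoded genes (median 0.13), 0 of 15 were called over all genes and 4 were higher over the list alone, and of the S-phase genes (median 0.08) 0 by either count. All 10 camera calls were lost with an estimated correlation, at adjusted p = 0.30 for each of these 3 lists.

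The effects against the vector were also set against each other over 14571 genes. Genes are not independent replicates, and the comparisons share the vector libraries. The log2 fold changes of Malt1_PD correlated with those of Malt1_WT at r = 0.87, those of Malt1_V87R at 0.57 and those of Malt1_L88D at 0.60, where 20 simulations of unchanged groups against simulated vector libraries gave means of 0.48, 0.49 and 0.48. The covariances were 0.453, 0.180 and 0.197, and the simulated covariance was 0.0189 in each case. Malt1_PD shared 2817 raised and 2723 lowered genes with Malt1_WT (901.3 and 887.9 for independent lists), Malt1_V87R 823 and 553 (277.3 and 189.3), and Malt1_L88D 1037 and 982 (355 and 340.4). Genes called in opposite directions to Malt1_WT numbered 42 in Malt1_PD, 102 in Malt1_V87R and 126 in Malt1_L88D. Simulated groups shared at most 1 gene. With 3 vector libraries the controls cannot be split so that each comparison has 2 of its own. The simulated groups shared their controls too, so 0.0189 is the covariance that the spread of shared libraries gave there. Beyond it the covariances were 0.434, 0.161 and 0.178. Part of this excess may still come from the shared controls if the vector libraries deviate together, which the simulations do not cover. In a pair added after seeing the data, Malt1_V87R and Malt1_L88D correlated at 0.81 (0.50 simulated) and shared 869 raised and 540 lowered genes (91.6 and 57.6 for independent lists). In that pair 0 genes were called in opposite directions.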

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

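Upper-quartile scaling and no scaling factor were chosen after seeing the data. The other settings were planned. Of 707 named-gene results, 638 kept their call in every alternative run, and of 11289 values 11045 stayed on the same side, 244 were no longer called and 0 changed direction. Malt1 against the vector or the wild type stayed called in every alternative, from 2.81 to 2.91 on the log2 scale for Malt1_WT against vector. With only the 6 libraries compared, Malt1 was also called between Malt1_V87R and Malt1_L88D (log2 0.15, adjusted p = 0.0217, with 0.0217 to 0.996 over its alternatives); the cause was not tested. Across settings other than leaving out a library, Malt1_WT against vector had 7611 to 8284 genes, Malt1_PD against vector 5681 to 6858, Malt1_PD against Malt1_WT 2583 to 3864, Malt1_V87R against Malt1_WT 6586 to 7380 and Malt1_L88D against Malt1_WT 6201 to 7078. Leaving out each library in turn, with fewer samples, gave 1130 to 1924 genes for Malt1_V87R against vector (lowest without Malt1_V87R replicate 2, highest without vector replicate 2), 1545 to 2854 for Malt1_L88D against vector (lowest without vector replicate 1, highest without vector replicate 2), and 0 to 2 between the death-domain mutants (2 without Malt1_L88D replicate 1). That comparison gave 5 genes with no filter and 25 with only the 6 libraries compared, and the cause was not tested. With replicate number as a block, Malt1_WT against vector had 8284 genes, 706 of 707 named-gene calls stayed and 117 of 118 list calls stayed (the MALT1 complex in Malt1_PD against vector went to adjusted p = 0.0585). Libraries of the same number correlated at a median r of 0.019 over 30 pairs, against -0.008 for other pairs. Of 15 libraries, 9 correlated best with their own number, so a weak effect shared by number is not excluded. The block also gave more genes in the other comparisons that had calls, such as 2146 against 1704 for Malt1_V87R against vector. Of 118 list calls, 60 held with an estimated correlation and 103 with the directional test of fry, and 100 held in every other setting of the same set test. Keeping only genes of 1 CPM in 3 libraries, thus fewer genes of low count, the correlation of effects was 0.897 for Malt1_PD with Malt1_WT, 0.601 for Malt1_V87R and 0.631 for Malt1_L88D. Leaving out each vector library gave 0.589 to 0.6 for Malt1_V87R and 0.616 to 0.628 for Malt1_L88D. Depth limits genes with few counts, such as Ifng.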

Other observations

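The tests of the Malt1 level, of T and NK cell markers, and all 3 on Malt1_V87R and Malt1_L88D were chosen after the result was seen. The test of library scaling used upper-quartile scaling and no scaling factor, settings added after the data were seen, with its bound set before its own result was seen.

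Genes of the extracellular matrix and of the hypoxia response were split within their lists. In Malt1_WT against vector, 9 of 27 mesenchymal and matrix genes rose and 15 fell, the same over the list alone. The protease gene Mmp3 rose 12.0-fold and the matrix glycoprotein Tnc 5.14-fold, while Col6a1 was at 0.540 of the vector level. The list's median was -0.26 and its mean 0.20, camera was not significant (Down, adjusted p = 0.28) and fry pointed up. In Malt1_PD against vector, 9 rose and 10 fell, or 9 and 11 over the list alone, with a median of -0.07 and a mean of 0.30. Against Malt1_WT the list had a median of 0.19 and a mean of -0.18 in Malt1_V87R and 0.17 and -0.16 in Malt1_L88D. Of 34 hypoxia and glycolysis genes, 18 rose and 11 fell in Malt1_WT, the same over the list alone (adjusted p = 0.26 with an estimated correlation, so the camera call was lost). The peptide hormone adrenomedullin gene Adm was at 457 ± 22.6 against 115 ± 1.56 CPM and the growth inhibitor Ddit4 at 513 ± 19.8 against 159 ± 4.74 CPM. Of 14 YAP/TEAD targets 9 rose and 2 fell, and of 17 genes of the MALT1 complex and its kinases 10 rose and 3 fell, the same over each list alone. The second list holds Malt1 itself, so the construct fixes 1 of its rises and adds to its camera call. Both calls were lost with an estimated correlation (adjusted p = 0.11 and 0.10).

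Genes of oxidative phosphorylation fell in 25 of 30 cases in Malt1_WT against vector, or 26 with 1 rise over the list alone, ribosomal protein genes in 33 of 39, or 37, and ribosome biogenesis genes in 16 of 24 with 1 rise, the same over the list alone. These calls were lost with an estimated correlation (adjusted p = 0.26, 0.42 and 0.32). In Malt1_PD against Malt1_WT, 19 of 30, 30 of 39 and 11 of 24 of them were higher (1 lower in the last), or 21, 38 and 12 over the list alone, and these calls were lost too (adjusted p = 0.29, 0.38 and 0.32 with an estimated correlation). The mitochondrial ribosomal RNA mt-Rnr1 was at 507 ± 25.0 CPM in Malt1_WT against 982 ± 14.6 with the vector and 1020 ± 49.4 in Malt1_PD, and the mitochondrially encoded list was not called in Malt1_WT (camera adjusted p = 0.18), with 2 up and 6 down. Epithelial genes rose in 5 of 12 cases and fell in 3 (camera adjusted p = 0.35), fibroblast markers in 3 of 10 with 4 falls (0.73) and endothelial markers in 4 of 7 (0.18), the same over each list alone. S-phase genes fell in 2 of 30 cases in Malt1_V87R and 13 in Malt1_L88D against vector, or 1 and 15 over the list alone, calls lost with an estimated correlation (adjusted p = 0.48 and 0.12). Lyz2 was at 13.7 ± 7.34 CPM in Malt1_L88D and 5.66 ± 0.064 CPM with the vector.

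Of 40 interferon-stimulated genes, 21 were lower and 7 higher in Malt1_PD than in Malt1_WT, a camera call lost with an estimated correlation (adjusted p = 0.28), and Cxcl9, Gbp4, Iigp1 and Cd274 were among the 6 largest falls. A lower Malt1 transcript level is argued against as the cause of these falls, since Malt1 was higher in Malt1_PD by 0.307 on the log2 scale. Interferon gamma transcribed by the cells is argued against as well, with 0 Ifng counts over the 3 Malt1_WT libraries, where a count of 0 allows up to 3. The interferon beta gene Ifnb1 had 8 counts in Malt1_WT, 14 in Malt1_PD, 13 with the vector, 13 in Malt1_V87R and 3 in Malt1_L88D. Ifna1 had 0 in every group, and neither gene was tested as a cause. T and NK cell markers summed to 2.23 CPM more in Malt1_WT than with the vector, with Lck at 2.79 against 1.64 CPM, but Cd3e was at 0.0383, Gzmb at 0.0428, Nkg7 at 0 and Ptprc at 0.0837 CPM in Malt1_WT, the last against 0.128 CPM in Malt1_PD. The marker sum was 4.449 ± 0.498 CPM in Malt1_WT, 3.712 ± 0.452 in Malt1_PD, 2.703 ± 0.596 in Malt1_V87R and 2.83 ± 0.379 in Malt1_L88D. Against Malt1_WT the interferon-stimulated list was not called in Malt1_V87R or Malt1_L88D, with 12 members higher and 10 lower in each. Across the mutants the marker sum thus did not follow the list, although Cxcl9 was lower than in Malt1_WT in all of them. No T cells were added per the series title. These low marker levels do not decide whether a few such cells were present, and the PD mutation itself stays open, untested.

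Between Malt1_V87R and Malt1_L88D edgeR called 0 genes, with 852 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, while edgeR called 25 with only the 6 libraries compared, 5 with no filter and 2 without Malt1_L88D replicate 1. The same counts entered under both names is argued against, because the library totals differ. They were 19.53, 21.46 and 19.86 M in Malt1_V87R and 15.76, 20.74 and 16.7 M in Malt1_L88D. The closest pair across the names had a chi-square per degree of freedom of 1.823 against 1.615 for the closest pair within a group. That measure grows with depth and replicate pairs vary in it, so these values do not decide the question. As a whole, pairs across the names were about as close as replicates, with a median of 2.168 against 2.207 within groups. Too little precision to see 1.5-fold changes is argued against for genes with a mean of at least 5 CPM. Of these, 98.7% had a 95% interval of the difference within 1.5-fold. In simulated data 80% of 1.5-fold changes were recovered. Many genes were changed at once there, which eases the adjusted threshold, so that share may not hold where few genes differ. Of the smallest simulated changes 44% were recovered, so too little precision for changes of that size stays open. A common cell population behind both names stays open, since the counts do not read the substitutions and neither the 5.8% of genes at an unadjusted p under 0.05 nor calls that come and go with the setting decide it.

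G2/M genes were lower in Malt1_WT than with the vector, with a list median of -1.777. The choice among the scalings tried is argued against as the cause, since the highest median under the other scalings was -1.765. These scalings differed little, with medians over all genes from -0.045 with no scaling factor to 0.001 with RLE scaling. The test could therefore hardly have come out otherwise, and it bears only on the choice among them. A trend with GC content and transcript length is argued against, since the median was -1.896 after that trend was taken away, with values for all 29 genes. A lower share of dividing cells may be behind it, as a hypothesis that was not tested, since culture density and growth were not analysed here.

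For each comparison, 10 splits of its 6 libraries are too few for a share under 0.05. Every split other than the real one also mixes libraries of both groups. A real difference then adds to the spread within the mixed groups, so low counts there do not measure what chance gives. In the 7 comparisons other than Malt1_V87R against Malt1_L88D, 1 of the 10 splits, the real one, reached the real count. The real count and the highest of the other splits were 7997 and 0 for Malt1_WT against vector, 6521 and 1 for Malt1_PD, 1704 and 0 for Malt1_V87R and 2535 and 0 for Malt1_L88D. Against Malt1_WT they were 3399 and 0 for Malt1_PD, 7036 and 0 for Malt1_V87R and 6569 and 0 for Malt1_L88D. Between Malt1_V87R and Malt1_L88D both were 0, so all 10 splits reached the real count.

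Some libraries lay farther from their own group than others did. By the median chi-square per degree of freedom between pairs of libraries, a measure that grows with depth, Malt1_PD replicate 2 was at 4.033 from replicate 1 and 3.094 from replicate 3, which were at 2.081 from each other. It was at 3.933 from Malt1_WT replicate 2. Vector replicate 2 was at 3.363 from replicate 1 and 2.373 from replicate 3, against 2.224 between those, and at 2.971 from Malt1_V87R replicate 1. By the correlation of log CPM over genes, which are not independent replicates, vector replicate 2 was closer to vector replicate 1 (0.9922) than to that Malt1_V87R library (0.9889). Malt1_PD replicate 2 was likewise closer to Malt1_PD replicate 1 (0.9913) than to Malt1_WT replicate 2 (0.9882).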
